A study of Homo sapiens with 12 samples.

How the data were processed

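Polyadenylated RNA of HepG2 cells, an established human liver cancer line, was sequenced from 12 libraries in 4 groups of 3 biological replicates. The cells were exposed to 0.001 µM 2,4-D, a phenoxy herbicide, for 0, 10, 30 or 360 min. Per the labels' protocols, cells were detached with trypsin, RNA was extracted with Trizol and captured on oligo-dT beads, and cDNA was made by reverse transcription. The authors deposited 1 table of whole-number read counts per gene with 60612 gene rows and 12 columns, each of which carries the title of 1 sample. Per the submitters' processing notes, HISAT2, DESeq2 and the GRCh38 build were used; their versions and roles, the counting program, the annotation release, the read length and the use of strand are not given in the sources used here. Counts of genes that overlap on opposite strands, of readthrough gene models and of near-identical copies such as HSPA1A and HSPA1B are therefore uncertain. Such overlaps were not looked up for every gene named.

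Gene identifiers were matched to GENCODE release 29 on GRCh38, and 58394 of the 60612 (96.34%) were found. Positions, gene types, transcript lengths and GC content come from that release. Total counts per library ran from 29.8 to 83.5 in units of 1e6, and 3 counts, the floor below which a count of 0 says little, corresponded to 0.0359 to 0.101 counts per 1e6 counts (CPM). These floors cover counting error only, since the reads carry no molecular identifiers in the sources used here.

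The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 17779, and libraries were scaled by TMM (factors 0.981 to 1.014). A quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries, with 8 residual degrees of freedom. The common dispersion was 0.00945, a biological coefficient of variation of 9.7%. Each of the 3 exposure times was compared with 0 min, and consecutive times were compared with each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes given with the results come from this edgeR test unless another tool is named, tests are two-sided, and the p-values measure the spread between these biological replicates. The standard error (SE) of a log2 fold change was taken as its absolute value divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD with n = 3 per group.

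Before the data were examined, 38 gene lists, the rule for named genes and the alternatives were fixed, except for the alternatives said to have been added later. The lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists of a comparison. Every list with at least 5 measured members was tested. Counts of list members are given both over all genes and adjusted over the list alone. The camera test was repeated with the correlation estimated from the data. Genes were named from those called, with a mean log2 CPM of at least 1 and all 3 exposed libraries on the same side of all 3 untreated ones. The 12 with the largest change in each direction were eligible for each comparison with 0 min, and the 3 largest for consecutive times. Where fewer than 3 passed in a direction, the 3 with the smallest p were named as values, and up to 4 members with the smallest p were eligible in each list.

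The test was checked on simulated data drawn from the real genes' means, library sizes and dispersions, with 200 genes changed in each of 3 runs per comparison. The changed genes were drawn only from those with a log2 mean CPM of at least 1. Recovery of genes with lower counts was thus not measured. For 30 min against 0 min (17562 to 17574 genes per run), 129 of 201 genes changed 1.3-fold, 164 of 201 changed 1.5-fold and 185 of 198 changed 2-fold were recovered. For 360 min against 0 min (17554 to 17586 genes), these were 121 of 201, 158 of 201 and 190 of 198. For 10 min against 0 min (17585 to 17594 genes), these were 132 of 201, 170 of 201 and 188 of 198. The 3 runs for 10 min held 512 calls together, while 3 genes were called in the real data. The adjusted threshold was thus easier to pass in the runs, and recovery at 10 min in the real data may be lower. Genes were also drawn independently of each other in all runs. The share of false calls was 4.3% at 10 min, 4% at 30 min and 3.5% at 360 min.

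Alternatives were DESeq2 1.42.0, limma voom, RLE and total-count scaling, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries and at least 100 counts in total), the compared groups alone, the replicate number as a block, other thresholds and the omission of each library. Alternatives added after seeing the data were a term for a split of the libraries by mitochondrial share, the libraries below that gap alone, libraries thinned to the smallest total, removal of a trend on GC content, and the omission of untreated replicates 2 and 3. No column of the table was left out. Also added was a score per library for immediate early genes, the median over members of log2 CPM less the gene's mean at 30 min, compared between groups by a linear model with libraries as units.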

Results

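Gene expression was measured in HepG2 cells, a human liver cancer line that retains many hepatocyte functions, after exposure to 0.001 µM 2,4-D (2,4-dichlorophenoxyacetic acid, a synthetic auxin herbicide). Cells at 0 min were compared with cells exposed for 10, 30 and 360 min, with 3 biological replicates each, to follow the response over time at 1 dose. Total counts, in units of 1e6, were 37.2, 66.8 and 52.0 for the 0 min replicates, 29.8, 30.5 and 31.5 at 10 min, 83.5, 69.2 and 35.6 at 30 min, and 68.4, 33.4 and 64.0 at 360 min. No untreated libraries from 10, 30 or 360 min were analysed here, so each comparison with 0 min holds both the exposure and the time that passed.

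The share of counts from the mitochondrial genome separated the libraries in a way that followed the groups only in part. All 10 min libraries lay on the same side, and the other groups had libraries on both. It lay between 3.55% and 4.39% in 7 libraries (0 min replicate 1, all 10 min replicates, 30 min replicates 2 and 3, and 360 min replicate 3) and between 2.52% and 2.74% in the other 5. With this split as a term beside the exposure time, 127 genes differed between the sides, 17 of them mitochondrially encoded. The values with this term are given beside the counts of changed genes below. In comparisons with 10 min the term removes a difference between the sides that was measured only within the other groups.

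At 10 min 3 of 17779 genes passed the test against 0 min, 2 higher and 1 lower. TXNIP, which encodes a thioredoxin-binding protein that limits glucose uptake (chromosome 1, 145992435 to 145996600, minus strand), rose by 0.47 ± 0.05 (log2 fold change ± SE, adjusted p = 0.0053), from 57 ± 3.4 to 79 ± 4.5 CPM (SD, n = 3). DHRS2, a short-chain dehydrogenase, rose by 0.23 ± 0.03 (adjusted p = 0.017). IER3, an immediate early gene on chromosome 6 (30743199 to 30744554), fell by 0.53 on the log2 scale (SE 0.06, adjusted p = 0.013), from 144 ± 11 to 99.9 ± 0.61 CPM. IER3-AS1 overlaps it on the opposite strand (30742929 to 30743592), and reads of the pair cannot be told apart without strand. DHRS2 was not called without 0 min replicate 2 or 3 or 10 min replicate 1 or 3 (adjusted p up to 0.12), with the split term (0.071), with the 2 groups alone (0.16) or without a filter (0.057), nor IER3 without 10 min replicate 1 or 3 (adjusted p up to 0.065). With replicate 1 as the lone untreated library, an alternative added after seeing the data, none of the 3 was called (adjusted p 0.062 for TXNIP, 0.13 for DHRS2 and 0.054 for IER3). Next in line were FAXDC2 at 0.31 ± 0.05 (adjusted p = 0.081), FOSB at -3.93 ± 0.66 (adjusted p = 0.11) and PDRG1 at -0.25 ± 0.04 (adjusted p = 0.11), which did not pass. DESeq2 called each of them, and FOSB was called under 3 of 18 alternatives.

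Members of the hypoxia response list lay above 0 min at 10 min, with a median log2 fold change of 0.21 over 24 measured genes. None passed over all genes, and 15 were higher adjusted over the list alone. Examples are PFKFB4, a regulator of glycolysis, at 0.39 ± 0.06 (adjusted p = 0.11), the mitophagy receptor BNIP3L at 0.31 ± 0.05 (adjusted p = 0.11) and MXI1 at 0.27 ± 0.05 (adjusted p = 0.12). The list was called by camera (adjusted p = 3.7e-13), but not with an estimated correlation (adjusted p = 0.28). PFKFB4 belongs to the glycolysis list as well, so that list is not separate evidence. Glycolysis genes had a median of 0.10, with 0 of 23 past the threshold over all genes and 6 higher adjusted over the list alone (camera adjusted p = 3.8e-08; adjusted p = 0.29 with an estimated correlation). Immediate early genes, which respond to stimuli without new protein synthesis, had a median of -0.42, with 1 of 24 lower over all genes and 15 lower adjusted over the list alone (camera adjusted p = 5e-10; adjusted p = 0.29 with an estimated correlation). The 0 min replicates were far apart for several of these genes, and FOS stood at 14.1, 106 and 136 CPM in untreated replicates 1, 2 and 3. Without 0 min replicate 1 the list's median was -0.51, with 11 of 24 members lower over all genes. In the main test FOS at -3.07 ± 0.59 and JUN at -1.60 ± 0.29 did not pass (adjusted p = 0.12 for both). Each was called under 3 of 18 alternatives, DESeq2 among them. With replicate 1 as the lone untreated library the list's median was -0.13, a value that rests on 1 untreated library.

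The other lists called at 10 min moved less. Those that camera called higher were the secreted proteins of hepatocytes (median 0.05, adjusted p = 0.00027; adjusted p = 0.45 with an estimated correlation), the TCA cycle (0.04, 0.0099 and 0.29), gluconeogenesis and glycogen (0.03, 0.036 and 0.48) and fatty acid and triglyceride synthesis (0.03, 0.038 and 0.68), with the values in the same order. Called lower were the heat shock response (-0.06, 0.0017 and 0.48), p53 targets (-0.09, 0.0028 and 0.28) and DNA replication (-0.03, 0.022 and 0.48). None of these 7 lists had a member past the threshold over all genes; adjusted over the list alone 4 heat shock genes and 2 p53 targets were lower, and 1 gluconeogenesis gene and 1 fatty acid gene were higher. The call of DNA replication was lost without 0 min replicate 2 or 3 or 10 min replicate 3 (adjusted p 0.16, 0.053 and 0.21) and that of the TCA cycle without 10 min replicate 1 (0.056). Gluconeogenesis lost it without 0 min replicate 1 or 10 min replicate 1 or 3 (0.40, 0.19 and 0.12), and fatty acid synthesis without 0 min replicate 1 or 10 min replicate 1 or 2 (0.12, 0.35 and 0.13). Against untreated replicate 1 alone, the calls of the heat shock response, p53 targets, DNA replication and fatty acid synthesis were lost (0.78, 0.077, 0.73 and 0.052). Total-count scaling ended the calls of the TCA cycle, gluconeogenesis and fatty acid synthesis (0.082, 0.058 and 0.12), and the stricter filter that of gluconeogenesis (0.058). Of the 10 lists called at 10 min, fry called hypoxia, glycolysis and p53 targets. The 13 mitochondrial mRNAs had a median of 0.26 and were not called (adjusted p = 0.21), and all 10 min libraries were on the side with the higher mitochondrial share. The count of changed genes depended on the tool and on single libraries. DESeq2 called 174 genes and limma voom 3, and the split term gave 4, of which 2 were among the 3 genes above. An unadjusted p under 0.05 was found for 1941 genes at 10 min and 1652 at 30 min. In 15.5% of the genes tested the 10 min libraries did not overlap those at 0 min, against 10% by chance. Without 0 min replicate 1 the count was 25, without 10 min replicate 2 it was 13, and without 10 min replicate 1 it was 1.

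At 30 min, 136 genes differed from 0 min, 32 higher and 104 lower. IER3 fell by 1.41 (SE 0.06, adjusted p = 1.4e-07), from 144 ± 11 to 54.1 ± 3.9 CPM. IER3-AS1, which overlaps IER3, fell by 1.29 (SE 0.2, adjusted p = 0.0075). DDIT4, an inhibitor of mTORC1 signalling (chromosome 10, 72273920 to 72276036), fell by 1.35 (SE 0.06, adjusted p = 1.4e-07), from 145 ± 7 to 56.9 ± 3.2 CPM. DDIT4-AS1, inside DDIT4 on the opposite strand, fell by 1.28 (SE 0.08, adjusted p = 4.1e-06). BHLHE40, a transcriptional repressor of the circadian clock, fell by 1.66 (SE 0.10, adjusted p = 3.6e-06). The AP-1 subunit genes FOS and FOSB fell by 4.82 (SE 0.64) and 5.28 (SE 0.70), both with an adjusted p of 0.0026, and limma voom did not call either (adjusted p = 0.15 for FOS and 0.27 for FOSB). Against untreated replicate 1 alone FOSB was at -2.41 (adjusted p = 0.012).

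Of 24 measured immediate early genes, 13 fell and 0 rose at 30 min over all genes, and 20 were lower and 1 was higher adjusted over the list alone. The median log2 fold change was -0.67 (camera adjusted p = 8.2e-26; adjusted p = 0.10 with an estimated correlation). ZFP36, which encodes a protein that promotes decay of AU-rich mRNAs, fell by 1.13 (SE 0.14, adjusted p = 0.0015), JUNB by 1.04 (SE 0.14, adjusted p = 0.0026) and CCN1 by 1.87 (SE 0.29, adjusted p = 0.0075), the last not called with the 2 groups alone (adjusted p = 0.077). JUN fell by 1.67 (SE 0.28, adjusted p = 0.013), a call lost on the omission of any library except 0 min replicate 1, with adjusted p up to 0.082 over the omissions and 0.19 over all alternatives. With untreated replicates 2 and 3 left out, the list's median was -0.48, with 4 members lower over all genes and 15 adjusted over the list alone. FOS was then at -2.24 and IER3 at -1.40, both called, while CCN1 (-0.72, adjusted p = 0.084), JUN (-0.49, 0.19), JUNB (-0.65, 0.096) and ZFP36 (-0.80, 0.05 after rounding) were not.

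**Figure D1:**
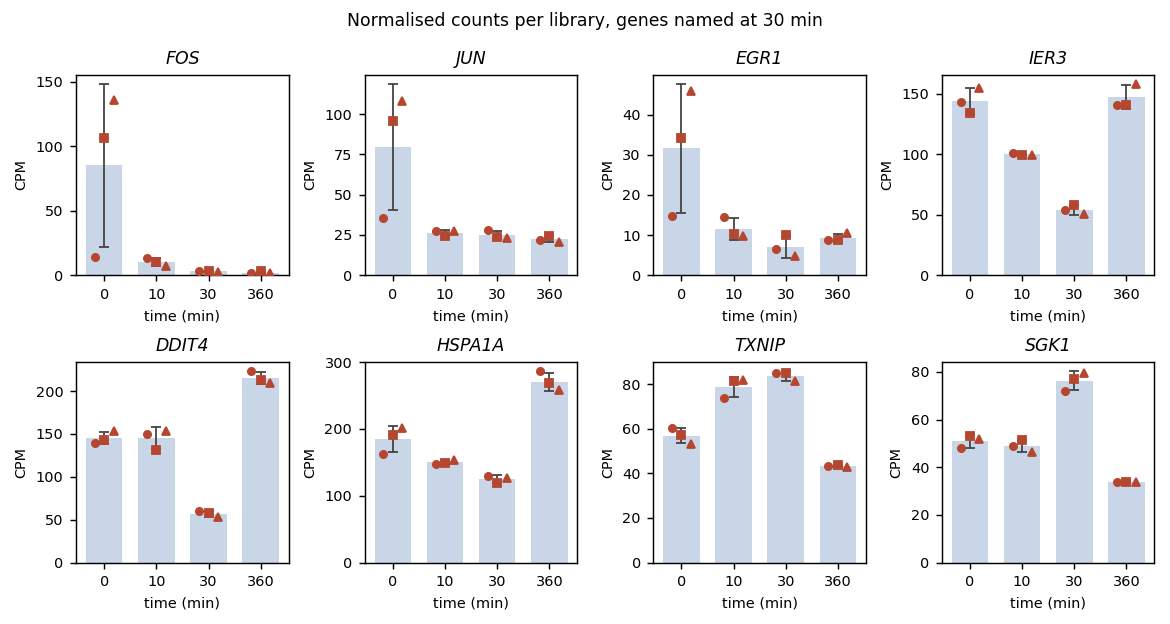
Normalised counts (CPM, linear axes from 0) of 8 genes against time in min; bars are group means, error bars are SD (n = 3), and circles, squares and triangles are replicates 1, 2 and 3. DDIT4 lay at 145 ± 7 CPM at 0 min and 56.9 ± 3.2 at 30 min, and untreated replicate 1 stood below replicates 2 and 3 for FOS (14.1 against 106 and 136 CPM).

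Some members of other stress lists fell as well at 30 min, while the list medians were small. They were -0.07 for heat shock genes and for p53 targets, -0.06 for hypoxia, and -0.02 for endoplasmic reticulum and for glycolysis genes. Among 20 measured heat shock genes 4 fell and 0 rose, and 8 were lower adjusted over the list alone (camera adjusted p = 3.9e-11; adjusted p = 0.12 with an estimated correlation). The near-identical HSP70 genes HSPA1A and HSPA1B, between which reads cannot be assigned with certainty, fell by 0.57 and 0.55 (SE 0.06 for both; adjusted p = 0.00092 and 0.00089). Of the p53 targets, 2 of 25 fell and 3 were lower adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.10 with an estimated correlation). GDF15, a stress-induced cytokine gene, fell by 0.62 (SE 0.04, adjusted p = 1.4e-05). The other p53 target that fell, BTG2 (adjusted p = 0.041), is also in the immediate early list. It lost the call in 5 of the 6 omissions of a 0 or 30 min library. In the hypoxia list 4 of 24 fell and 7 were lower adjusted over the list alone (camera adjusted p = 7.9e-05; adjusted p = 0.69 with an estimated correlation). The vasodilator peptide gene ADM fell by 0.99 (SE 0.09, adjusted p = 2e-04) and the angiogenic factor gene VEGFA by 0.44 (SE 0.06, adjusted p = 0.0023). Endoplasmic reticulum genes (1 of 23 lower) and glycolysis genes (2 of 23 lower) were called lower by camera (adjusted p = 0.014 and 0.037), each with an adjusted p of 0.69 with an estimated correlation and with 1 and 2 lower adjusted over the list alone. The first was not called without 0 min replicate 2 or 3 or 30 min replicate 1 (adjusted p 0.072, 0.14 and 0.15), nor the second without 0 min replicate 2 or 3 or 30 min replicate 2 (0.27, 0.066 and 0.33) or with the split term (0.068). FOXA2, a hepatocyte transcription factor gene, fell by 0.28 (SE 0.04, adjusted p = 0.0056). Against untreated replicate 1 alone, the lists of hypoxia, endoplasmic reticulum and glycolysis genes were not called, nor were HSPA1B and FOXA2. With all libraries, fry did not call these lists either (adjusted p 0.15, 0.21 and 0.35 in the same order). FOXA2 was also not called with the 2 groups alone (0.061).

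Of the 32 genes that rose at 30 min, SGK1, a kinase regulated by glucocorticoids and osmotic stress, rose by 0.58 ± 0.05 (adjusted p = 1e-04), TXNIP by 0.56 ± 0.05 (adjusted p = 9.7e-05), DEPP1 by 0.72 ± 0.09 (adjusted p = 0.0025), the kinase gene PIM1 by 0.56 ± 0.07 (adjusted p = 0.0026) and the zinc exporter gene SLC30A1 by 0.45 ± 0.06 (adjusted p = 0.0036). The zinc finger gene ZNF551 rose by 0.93 ± 0.15 (adjusted p = 0.0098), from 2.47 ± 0.36 to 4.71 ± 0.44 CPM, and was not called without 30 min replicate 1 (adjusted p = 0.06; up to 0.071 over all alternatives). Among 17 nuclear-retained and snoRNA host RNAs 3 rose and 4 were higher adjusted over the list alone (camera adjusted p = 0.00052; adjusted p = 0.69 with an estimated correlation). The secreted proteins of hepatocytes were called higher (median 0.02, adjusted p = 0.044; adjusted p = 0.69 with an estimated correlation) with 0 of 49 members past the threshold over all genes or adjusted over the list alone. This call was lost without 0 min replicate 1 or 3 or 30 min replicate 1 (adjusted p 0.23, 0.098 and 0.58), with total-count scaling (0.054), with the stricter filter (0.062) and by fry (0.41). Against untreated replicate 1 alone, DEPP1 and PIM1 were not called, nor was the list of nuclear-retained and snoRNA host RNAs. With all libraries, fry did not call that list either (adjusted p = 0.25).

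The size of the 30 min set was sensitive to single libraries. The omission of any library other than 0 min replicate 1 lowered the count of 136: to 79 and 61 without 0 min replicates 2 and 3, and to 68, 79 and 73 without 30 min replicates 1, 2 and 3. DESeq2 gave 271. Camera called 8 lists, and 5 without 0 min replicate 3. The split term gave 133, and replicate 1 as the lone untreated library gave 52. In 14.5% of the genes tested the 30 min libraries did not overlap those at 0 min, against 10% by chance.

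At 360 min, 3215 genes differed from 0 min, 1581 higher and 1634 lower, with a median absolute log2 fold change of 0.26 among them. CYP1A1, the cytochrome P450 gene induced through the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), had the largest rise among genes that met the naming rule, by 1.62 ± 0.17 (adjusted p = 4.6e-05), from 2.72 ± 0.51 to 8.33 ± 0.36 CPM. The splicing kinase gene CLK1 rose by 1.03 ± 0.05 (adjusted p = 1.3e-07), CCNG2 by 0.86 ± 0.09 (adjusted p = 3e-05) and BIRC3, an inhibitor of apoptosis, by 0.82 ± 0.09 (adjusted p = 5e-05). CYP24A1, which inactivates vitamin D, fell by 1.94 (SE 0.08, adjusted p = 1.5e-08), and the transcriptional inhibitor genes ID1 and ID3 fell by 1.71 and 1.52 (SE 0.06 for both; adjusted p = 6.4e-09 and 1.2e-08). ID1 went from 203 ± 21 to 62 ± 1.7 CPM. PAQR8, a membrane progesterone receptor gene, fell by 1.40 (SE 0.05, adjusted p = 6.4e-09).

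**Figure D2:**
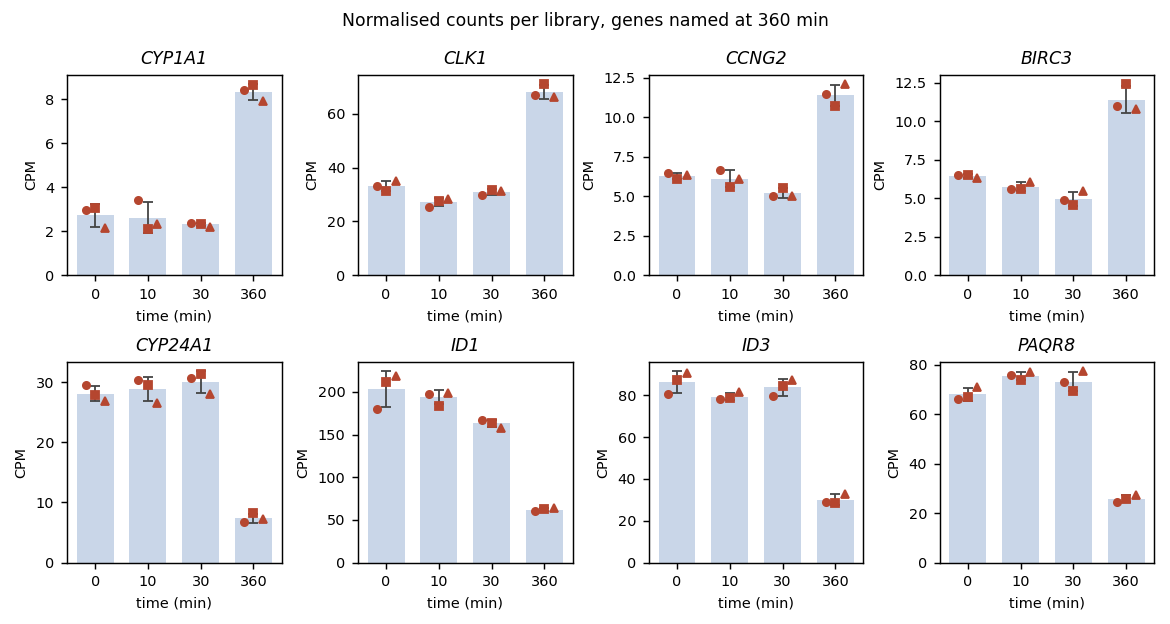
Normalised counts (CPM, linear axes from 0) of 8 genes against time in min; bars are group means, error bars are SD (n = 3), and circles, squares and triangles are replicates 1, 2 and 3. CYP1A1 reached 8.33 ± 0.36 CPM at 360 min against 2.72 ± 0.51 at 0 min, while ID1 went from 203 ± 21 to 62 ± 1.7 CPM.

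Lists of cell cycle genes and p53 targets were called higher at 360 min by camera with the preset correlation. Of 34 measured G2 and M phase genes 27 rose and 0 fell, and 29 were higher and 1 was lower adjusted over the list alone (median 0.26, camera adjusted p = 1e-15; adjusted p = 0.21 with an estimated correlation). The cytokinesis gene ANLN rose by 0.48 ± 0.04 (adjusted p = 5.8e-06), the topoisomerase gene TOP2A by 0.38 ± 0.04 (adjusted p = 3.9e-05) and the spindle checkpoint gene BUB1B by 0.31 ± 0.03 (adjusted p = 4.4e-05). Among 38 DNA replication genes 17 rose and 6 fell, with 18 and 7 adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.49 with an estimated correlation). This call was lost without 0 min replicate 1 or 360 min replicate 1 (adjusted p 0.09 and 0.056), with total-count scaling (0.057) and with the stricter filter (0.08). LIG1 rose by 0.40 ± 0.04 (adjusted p = 1.8e-05), while E2F2 fell by 0.40 (SE 0.04, adjusted p = 4.6e-05). Of 25 p53 targets 14 rose and 0 fell, with 16 higher adjusted over the list alone (median 0.21, camera adjusted p = 8.1e-07; adjusted p = 0.053 with an estimated correlation). MDM2, the ubiquitin ligase that targets p53, rose by 0.40 ± 0.04 (adjusted p = 3.8e-05) and the death receptor gene FAS by 0.52 ± 0.06 (adjusted p = 0.00011).

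Lists of protein folding and degradation genes were also called higher at 360 min by camera with the preset correlation. In the heat shock list 12 of 20 rose and 2 fell, with 12 and 3 adjusted over the list alone (median 0.17, camera adjusted p = 0.00014; adjusted p = 0.33 with an estimated correlation). HSPH1 rose by 0.45 ± 0.04 (adjusted p = 2.4e-05) and the constitutive HSP70 gene HSPA8 by 0.45 ± 0.05 (adjusted p = 4.3e-05). Of 31 proteasome genes 15 rose and 0 fell, with 17 higher adjusted over the list alone (median 0.10, camera adjusted p = 2.7e-06; adjusted p = 0.33 with an estimated correlation), such as PSMC6 at 0.24 ± 0.04 (adjusted p = 0.00093). Among 23 endoplasmic reticulum chaperone and unfolded protein response genes 8 rose and 2 fell, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.33 with an estimated correlation), including DNAJB9 at 0.52 ± 0.10 (adjusted p = 0.0029). Of 27 serine, glycine and one-carbon genes 6 rose and 0 fell, the same 6 in number adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.33 with an estimated correlation). Among 41 spliceosome genes 7 rose and 2 fell, with 10 and 3 adjusted over the list alone (camera adjusted p = 0.046; adjusted p = 0.49 with an estimated correlation). Of these lists, the one-carbon genes lost the call without 0 min replicate 1 or 3 or 360 min replicate 2 or 3 (adjusted p 0.056, 0.059, 0.07 and 0.058). The spliceosome genes lost it without 0 min replicate 1 or 3 or 360 min replicate 1 or 2 (0.056, 0.067, 0.11 and 0.06), and with replicate 1 as the lone untreated library (0.11). Total-count scaling and the stricter filter also ended both calls (0.057 and 0.075 for one-carbon genes, 0.09 and 0.081 for the spliceosome). SRSF2 rose by 0.57 ± 0.04 (adjusted p = 3.6e-06).

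Immediate early genes were still lower at 360 min than at 0 min, with 16 of 24 lower and 1 higher both over all genes and adjusted over the list alone (median -0.64, camera adjusted p = 8.1e-07; adjusted p = 0.33 with an estimated correlation). FOS fell by 5.42 (SE 0.68, adjusted p = 0.00016) and CCN1 by 2.42 (SE 0.30, adjusted p = 0.00014), against untreated libraries of which replicate 1 was low. KLF10 fell by 0.69 (SE 0.07, adjusted p = 4.6e-05). With replicate 1 as the lone untreated library the median was -0.39, with 11 members lower over all genes, and FOS, CCN1 and KLF10 were at -2.78, -1.26 and -0.55, all called.

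The following lists of liver metabolism and stress genes were not called by camera at 360 min, and fry called 3 of them. Of 21 fatty acid and triglyceride synthesis genes 3 rose and 8 fell, with 5 and 10 adjusted over the list alone (adjusted p = 0.072), among them ACSS2, which fell by 0.53 (SE 0.04, adjusted p = 1.9e-06). In the AhR target list CYP1A1 was the 1 gene of 8 that rose, and NQO1 and ALDH3A1 fell by 0.17 (SE 0.03, adjusted p = 0.0016) and 0.47 (SE 0.09, adjusted p = 0.0037). ALDH3A1 was not called with thinned libraries (-0.33, adjusted p = 0.068) or in the libraries below the gap in mitochondrial share (-0.46, adjusted p = 0.072). AHR itself fell by 0.36 (SE 0.06, adjusted p = 0.00091). Among 23 cytochrome P450 and phase I genes 4 rose and 2 fell, with CYP3A7 higher by 1.21 ± 0.17 (adjusted p = 0.00033) and CYP2S1 lower at -0.75 ± 0.07 (adjusted p = 1.4e-05). In the NRF2 list 3 of 24 rose and 7 fell, and the heme oxygenase gene HMOX1 fell by 0.70 (SE 0.05, adjusted p = 4.1e-06). Bile acid genes included the FGF19 coreceptor gene KLB, which rose by 0.52 ± 0.04 (adjusted p = 5.8e-06), with 4 of 15 higher and 0 lower. By fry, fatty acid synthesis (adjusted p = 0.01) and NRF2 targets (0.025) were lower and bile acid genes higher (2.7e-05), while AhR targets (0.063) and phase I genes (0.71) were not called. Adjusted over the list alone, the numbers higher and lower were 1 and 2 for AhR targets, 5 and 2 for phase I genes, 3 and 7 for NRF2 targets and 4 and 2 for bile acid genes.

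Markers of cell types other than hepatocytes were not called as lists at 360 min by camera, while fry called the endothelial (adjusted p = 2.7e-05), fibroblast (2.7e-05) and squamous and cholangiocyte (0.032) lists lower. Of 7 measured endothelial markers 2 fell, ESAM by 0.82 (SE 0.05, adjusted p = 3.7e-07) and ENG by 0.74 (SE 0.06, adjusted p = 1.4e-05), with 3 lower adjusted over the list alone (camera adjusted p = 0.072). Of 8 fibroblast markers 1 rose and 3 fell, in the same numbers adjusted over the list alone (camera adjusted p = 0.13), with TAGLN, an actin-binding protein gene, lower at -0.65 ± 0.04 (adjusted p = 2.3e-07). Of 5 squamous and cholangiocyte markers 0 rose and 2 fell, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.4). None of 13 blood and immune markers was called by edgeR (list by camera adjusted p = 0.23, by fry 0.091). In the ribosomal protein list 0 of 75 genes were called (camera adjusted p = 0.23).

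**Figure D3:**
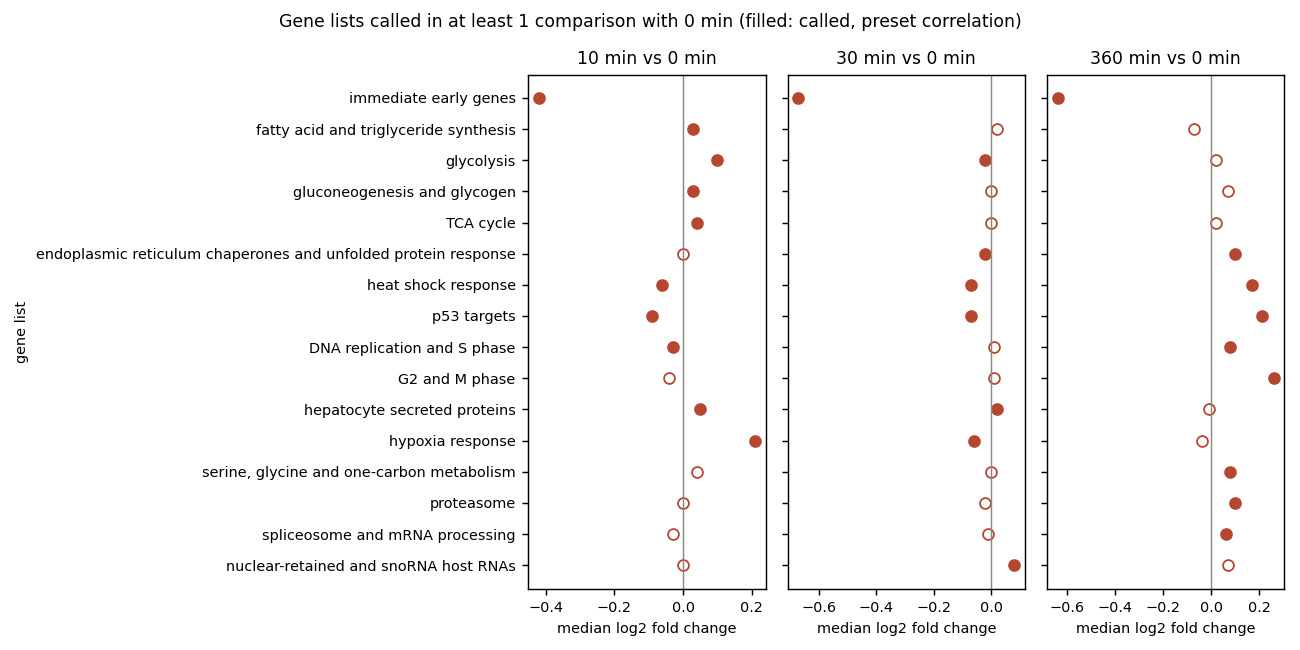
Median log2 fold change of the measured members (horizontal axes) of the 16 gene lists that camera called in at least 1 comparison with 0 min (rows), with 1 panel per comparison; filled points are calls with the preset correlation and open points are not called. Immediate early genes lay at -0.42, -0.67 and -0.64 at 10, 30 and 360 min, while G2 and M phase genes reached 0.26 at 360 min.

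The 360 min libraries did not overlap the 0 min libraries in 35.6% of the genes tested, against 10% by chance. With the split term 3422 genes were called, and in the 4 libraries below the gap in mitochondrial share 2699. With replicate 1 as the lone untreated library 1751 were called, and 145 of the 3215 changed at least 2-fold.

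Between 10 and 30 min, 102 genes differed, 29 higher and 73 lower at 30 min. DDIT4 fell by 1.35 (SE 0.06, adjusted p = 3.2e-07), from 145 ± 13 to 56.9 ± 3.2 CPM, BHLHE40 fell by 1.60 (SE 0.10, adjusted p = 6.2e-06), and ZNF551 rose by 1.05 ± 0.15 (adjusted p = 0.0081). The readthrough model SENP3-EIF4A1, which shares exons with EIF4A1, was higher at 1.26 ± 0.21 (adjusted p = 0.019), and was not called without 10 min replicate 1, 30 min replicate 1 or 30 min replicate 2 (adjusted p up to 0.089). The hypoxia list was lower at 30 min than at 10 min, with 9 of 24 members lower over all genes and 22 adjusted over the list alone (median -0.26, camera adjusted p = 7.5e-26; adjusted p = 0.057 with an estimated correlation). Glycolysis genes, whose list shares PFKFB4 with the hypoxia list, had 5 of 23 lower over all genes and 12 adjusted over the list alone. Camera gave the glycolysis list an adjusted p of 1.6e-12, and 0.17 with an estimated correlation. Of 38 lists 10 were called, 2 higher and 8 lower, and 0 of them with an estimated correlation. The count of genes was 78 with total-count scaling, 32 of them higher, 116 with the split term and 290 with DESeq2. It was 39 and 48 without 10 min replicates 1 and 3, and 51, 46 and 40 without 30 min replicates 1, 2 and 3.

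Between 30 and 360 min, 4034 genes differed, 2029 higher and 2005 lower at 360 min. DDIT4 rose by 1.92 ± 0.06 (adjusted p = 2.3e-09), from 56.9 ± 3.2 to 215 ± 7.1 CPM, and CYP1A1 rose by 1.85 ± 0.17 (adjusted p = 1.1e-05). CYP24A1 fell by 2.04 (SE 0.08, adjusted p = 1e-08) and PAQR8 by 1.5 (SE 0.05, adjusted p = 2.3e-09). Of 25 p53 targets 19 rose and 0 fell, with 21 higher adjusted over the list alone, and this list was called both with the preset correlation (camera adjusted p = 2.3e-10) and with an estimated one (adjusted p = 0.012), as 1 of the 6 lists called. DDIT4-AS1, an antisense gene inside DDIT4 (72274915 to 72275980), changed with it (1.90 ± 0.08, adjusted p = 1.8e-08), and reads of the pair cannot be told apart without strand. The split term gave 4023 genes.

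The comparisons with 0 min share the same untreated libraries, so their overlap is given beside that of simulated groups without any change. The 30 min and 360 min sets had 79 genes in common, 33 in the same direction and 46 in opposite directions. The highest value in 20 simulated runs was 0, but these runs hold no changed genes and so do not show what the shared libraries add when many genes change. Independent lists of these sizes would share 2.85 genes higher in both, where 5 were found, and 9.56 lower in both, where 28 were found. For genes lower at 30 min and higher at 360 min 9.25 would be shared and 35 were found, and for the reverse 2.94 and 11. These values take every tested gene as equally likely to be called, whatever its counts or spread. Part of an excess over them may come from that, which was not tested. Across genes, which are not independent replicates, the log2 fold changes at 30 and 360 min had a correlation of 0.502 against 0.491 in the simulation, a covariance of 0.0787 against 0.0371, and the same sign in 54% of genes against 66.7%. The 3 genes called at 10 min were all called at 30 min in the same direction, and of the 2 also called at 360 min 1 had the opposite direction. The 3 untreated libraries cannot be divided into parts of at least 2, so part of any excess in the same direction may come from them.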

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

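The tests with the mitochondrial-share split, the removal of the GC trend, the shared 0 min libraries, the score per library, untreated replicate 1 alone and the weighing of the early gene medians over omissions were chosen after the results were seen.

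Expression differed between time points, in 102 genes between 10 and 30 min and 4034 between 30 and 360 min by edgeR. Among named genes, 18 were called in opposite directions against 0 min at 30 and 360 min, which by itself makes them differ between these times, by the following log2 values. Higher at 360 min than at 30 min were DDIT4 (1.92 log2 units), DDIT4-AS1 (1.90), HSPA1B (1.14), BTG2 (1.13), HSPA1A (1.12), HERPUD1 (0.76), GDF15 (0.75), HSPH1 (0.73), BAG3 (0.57), FOXA2 (0.53), MAFG (0.52) and HNF4A (0.33). Lower at 360 min were DEPP1 (-1.30), SGK1 (-1.17), PIM1 (-1.03), TXNIP (-0.95), SLC30A1 (-0.75) and SNHG3 (-0.46). The 30 min calls of HERPUD1, HNF4A and BAG3 were lost on the omission of any 0 or 30 min library except 0 min replicate 1 (adjusted p up to 0.12, 0.18 and 0.097), that of BTG2 on any except 0 min replicate 3 (0.16) and that of MAFG on any except 30 min replicate 3 (0.17). SNHG3 lost it without 0 min replicate 2 or 30 min replicate 2 or 3 (0.065), and HSPH1 without 0 min replicate 3 or 30 min replicate 1 (0.054).

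Over all genes, 46 were called in opposite directions, 35 of them lower at 30 min and higher at 360 min. All 46 were called between 360 min and 30 min, but that contrast is the sum of the 2 opposite changes, so their selection fixed this outcome and a part played by chance deviations of the shared 0 min libraries stays open. With the mitochondrial-share split as a term, 41 of the 46 kept both calls. The split divides the 0 and 360 min groups alike, so the term could hardly move the 360 min changes. It tests the 30 min changes, for which the calls kept argue against the split as the whole cause. Time in culture and handling without the compound cannot be told apart from exposure, since 0 untreated libraries at 30 or 360 min were analysed here. A transient change followed by a return past the starting level is a candidate explanation that these data leave untested.

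Immediate early genes were lower at 30 min, with a median log2 fold change of -0.67 over 24 members that move together, and camera did not call the list with an estimated correlation (adjusted p = 0.10). If 1 untreated library with high early-gene RNA had caused this, leaving it out would bring the median near 0, but the medians were -0.83, -0.64 and -0.59 without untreated replicates 1, 2 and 3, and 1 score per library differed by -0.83 (SE between libraries 0.07), -0.69 (SE 0.12) and -0.62 (SE 0.10). With the mitochondrial-share split as a term the median was -0.62 and the score differed by -0.68 (SE 0.10). These SEs pool the spread of all groups and may understate that of the untreated libraries. The scores were 0.48, 0.77 and 0.9 in untreated replicates 1, 2 and 3, and 0.01, 0.07 and -0.08 at 30 min. High values in both untreated replicates 2 and 3 may add to the size of the change, since the median against replicate 1 alone was -0.48, and this rests on 1 library. Time in culture and handling without the compound, such as a response to handling that was still decaying at 0 min, cannot be told apart from exposure with 0 untreated libraries at 30 min.

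The 360 min changes covered 3215 genes, and log2 fold changes fell with transcript GC content (Spearman -0.235 across genes, which are not independent). After the GC trend between libraries was removed (Spearman -0.012), 2649 of the 3215 genes were still called in the same direction, so the trend as the whole cause is argued against. With the mitochondrial-share split as a term 3156 were still called in the same direction. The split divides the 0 and 360 min groups alike, so the term could hardly move these changes and the count is no separate test. Time in culture and handling without the compound, for instance growth or medium use over 360 min, cannot be told apart from exposure with 0 untreated libraries at 360 min, and 2,4-D exposure itself stays open and untested against it.

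Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real split was the 1 split of 10 with as many genes in all 5 comparisons. Every other split mixes libraries of both times on each side, so real differences widen the spread within sides and lower the counts. The other splits thus do not show how many genes would be called without any change. It gave 3 genes at 10 min (highest other split 2), 136 at 30 min (0), 3215 at 360 min (1), 102 for 30 against 10 min (2) and 4034 for 360 against 30 min (1). For gene lists, 2 of the 10 splits called at least as many at 10 min (10, highest other 14), 2 at 30 min (8, highest other 10) and 1 at 360 min (9, highest other 6). The split of the 0 and 30 min libraries that follows the mitochondrial share gave 0 genes and 3 lists, and that of the 30 and 360 min libraries gave 0 genes.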

How the results depend on the processing

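The split term, thinning, removal of the GC trend, the omission of untreated replicates 2 and 3 and the libraries below the mitochondrial-share gap were chosen after the results were seen. No named gene reversed under any alternative run. Of the called genes taken into these comparisons, 12 of 46 at 30 min and 91 of 102 at 360 min stayed called under all of them, and 23 of 46 and 98 of 102 under every omission of 1 library; the cause of each loss was not tested. For genes changed, DESeq2 gave 174 at 10 min, 271 at 30 min and 290 for 30 against 10 min, and the cause was not tested. With the 2 compared groups alone the counts were 7 at 10 min and 67 at 30 min, from fewer samples. At 10 min no filter gave 9. The replicate block gave 6 at 10 min against 3, and its other counts were 109, 3067, 75 and 3883. Deviations of same-numbered libraries of different groups correlated at -0.054 to 0.099 (median 0.028), against a median of -0.019 for other numbers. No clear pairing was thus seen, but such small values over all genes tested cannot exclude it. With replicate 1 as the lone untreated library the counts were 10, 52 and 1751 at 10, 30 and 360 min, with fewer samples. At an absolute log2 fold change of at least 1 they were 0, 18, 145, 12 and 202 for the 5 comparisons in the order of the report, and at an adjusted p under 0.01 they were 1, 62, 1718, 37 and 2256, by construction. Omission of 1 library gave 1 to 25, 61 to 163, 2281 to 2714, 39 to 83 and 3024 to 3481. For lists, camera with an estimated correlation called 0 at each time, fry, which asks whether a list's genes move one way, called 3, 4 and 18, and omission of 1 library gave 7 to 12, 5 to 9 and 6 to 10. With the replicate block camera called 10, 7 and 6 lists, against 10, 8 and 9 in the main test. For genes called at 2 times, DESeq2 gave 33 at 10 and 30 min in the same direction, 32 and 62 at 10 and 360 min in the same and opposite directions, and 61 and 82 at 30 and 360 min. The replicate block gave 2 at 10 and 360 min in the same direction. Libraries thinned to the smallest total gave 3, 119 and 2886 genes at 10, 30 and 360 min, of which 3, 105 and 2684 were called at full depth, and at 30 min 20 were higher against 32. Calls were thus lost at lower depth, and whether more depth would add calls was not tested. Alignment and counting with other programs were not run.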

Other observations

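The lists in this part were written after the named genes had been seen and before their tests were run, and these tests were not planned before the data were examined. They were run on all 12 libraries only, not under the omissions or the other alternatives.

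Genes that report bone morphogenetic protein (BMP) and SMAD signalling were examined at 360 min because ID1 and ID3 had fallen, and both were left out of the list. Of 12 measured genes 10 fell and 0 rose over all genes, and 11 were lower adjusted over the list alone, with a median log2 fold change of -0.69. ID2 fell by 0.72 (SE 0.07, adjusted p = 1.9e-05), the inhibitory SMAD gene SMAD6 by 0.58 (SE 0.08, adjusted p = 3.1e-04) and SMAD9 by 0.88 (SE 0.10, adjusted p = 8.6e-05), all by edgeR. The iron regulator gene HAMP fell as well, from 0.385 ± 0.0733 to 0.0614 ± 0.0333 CPM, near the floor of 3 counts. Camera called the list with an estimated correlation (adjusted p = 0.0021 over the 4 lists of this part). The hypothesis that BMP and SMAD signalling was lower at 360 min than at 0 min is consistent with this value, and elapsed time without the compound stays open.

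Negative feedback genes and other target genes of ERK signalling were examined as 1 list at 30 min, where immediate early genes had fallen. Of 15 measured genes 5 fell and 0 rose, and 7 were lower adjusted over the list alone, with a median of -0.16. SPRY4 fell by 0.77 (SE 0.06, adjusted p = 3.4e-05), the ERK phosphatase gene DUSP6 by 0.93 (SE 0.10, adjusted p = 5.7e-04) and EPHA2 by 0.43 (SE 0.04, adjusted p = 1.3e-04). ETV4 (-0.01 ± 0.03), ETV5 (-0.05 ± 0.04), SPRED1 (0 ± 0.06) and SPRED2 (0.03 ± 0.05) did not pass and lay near 0, and DUSP5 (0.40 ± 0.32) and SPRED3 (0.38 ± 0.57) did not pass either. FOSL1 belongs to this list and to the immediate early list. The fall of the ERK list was not tested against untreated replicate 1 alone or on the omission of any library. Camera with an estimated correlation gave an adjusted p of 0.0021, consistent with the hypothesis of lower ERK output at 30 min than at 0 min for part of the list, with handling of the 0 min cells left open.

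Feedback and other target genes of Wnt and beta-catenin signalling at 360 min had a median of -0.12. Over all genes 7 of 15 were lower and 1 was higher, and adjusted over the list alone 7 and 2. NKD1 fell by 0.65 (SE 0.04, adjusted p = 5.3e-07), TBX3 by 0.49 (SE 0.04, adjusted p = 1.2e-05) and CCND1 by 0.36 (SE 0.04, adjusted p = 3.2e-05). GLUL rose by 0.14 ± 0.03 (adjusted p = 0.0089), CYP2E1 stood at 1.26 ± 0.50 (adjusted p = 0.1 over all genes and 0.043 over the list alone), and AXIN2 was at -0.09 ± 0.05 (adjusted p = 0.23). With an estimated correlation the list was not called (adjusted p = 0.093), so the hypothesis of lower beta-catenin output is left undecided. For 387 zinc finger genes with ZNF symbols at 30 min, without ZNF551, ZNF134 and ZNF441, the median was 0.02, 1 rose, 0 fell and none was called adjusted over the list alone. Camera with an estimated correlation gave an adjusted p of 0.29, so a rise of this family along with those 3 genes was not seen.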
